A study of Mus musculus with 3 samples.

How the data were processed

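Single-cell RNA sequencing of mouse brain gave 3 libraries, 1 per group: an uninjured control (control), an injured brain with a GFP reporter vector (TBI-GFP) and an injured brain with a NeuroD1 vector (TBI-ND1), TBI being traumatic brain injury. The group names are those of the labels. Each deposited matrix holds counts, namely raw UMI counts per gene and cell barcode, which the authors had already limited to called cells. The aligner and the counting program are not given in the sources used here; the labels name the mm10 build and Seurat 3. The deposited gene and barcode tables hold other content, namely text identifiers with no unit. The authors also deposited a table of mean values per group on another scale, in which each column sums to 10000.

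The control matrix lists 32589 features, and each TBI matrix lists 53717 features, among them a GFP and an ND1 feature that the control table lacks. Genes were matched by identifier, and 31623 genes are present in all 3 tables, of which 1096 carry a different symbol in different tables. These shared genes hold 99.9% of the UMIs of control, 95.8% of TBI-GFP and 96.1% of TBI-ND1. Because the gene tables differ, 72 genes at 0 UMIs in the libraries of 1 table and at 1 CPM or more in the other were left out of the comparisons with control.

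Cells with at least 500 UMIs in shared genes, at least 300 genes and at most 20% mitochondrial UMIs were kept. Each library was clustered on its own with scanpy 1.11.5 (anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9) from 2000 variable genes, 30 principal components and 15 neighbours at Leiden resolution 1. Clusters were named "X-like" from marker genes of 16 cell classes fixed before the data were examined. A cluster with under 3 detected markers of its best class, or with more markers of another class than of its own among its 10 leading genes, stayed unnamed. So did a cluster of low UMI counts with no marker among its leading genes.

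Doublet scores were computed with the Scrublet method in scanpy. Its automatic threshold called 0 cells in control, 0 cells in TBI-ND1 and 2591 cells (6.45%) in TBI-GFP, so it was not used. In its place, clusters whose median score was above 2 times the library median were set apart as doublet-like, a rule chosen after the data were examined. The names and shares of cell classes rest on this rebuilt annotation and not on one by the authors.

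UMIs were summed per library and cell class and divided by the class total in shared genes, to give UMIs per 1000000 UMIs (CPM). Comparisons were TBI-GFP against control, TBI-ND1 against TBI-GFP and TBI-ND1 against control. A log2 ratio of CPM was taken with a prior of 1 count added to each sum, for genes with at least 20 summed UMIs over both libraries. With 1 library per group no test between groups was possible, and none was run. Intervals are 95% intervals that cover counting error only: exact Clopper-Pearson for shares of cells, exact Poisson for CPM, an exact conditional interval for the ratio of a single gene, and 200 Poisson resamples for a list median. A count of 0 was bounded by 3 counts.

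The 24 gene lists were fixed before the data were examined: pan-reactive, A1 reactive and A2 reactive astrocyte, homeostatic astrocyte, nuclear oxidative phosphorylation, mitochondrially encoded respiratory chain, glycolysis, hypoxia response, antioxidant, interferon response, cytokine and NF-kB, complement, MHC class I, MHC class II, homeostatic microglia, disease-associated microglia, phagocytosis receptor and lysosome, NeuroD1 and neurogenic, matrix and scar, astrocyte synapse support, cholesterol synthesis, proliferation, immediate-early and dissociation stress, and cytosolic ribosomal protein genes. Each list is described by the median log2 ratio of its measured members. Members were counted as higher or lower from a 1.5-fold ratio. Beside the median stands the percentile of that median among 10000 random lists of the same size, matched in 20 bins of expression. Genes were named by a rule fixed at the same time: up to 4 members with the largest absolute ratio in each list described, and the 10 genes highest and the 10 lowest by ratio among those with at least 50 CPM and 50 UMIs in the higher library. That second set leaves out genes below their level over all kept cells of that library, mitochondrial and ribosomal protein genes, haemoglobins, predicted genes, sex-linked genes and markers of other classes.

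The ratio and list steps were tested on simulated data made from the summed counts of each class with known changes. Apart from these changes, both libraries were drawn from the same Poisson rate per gene. The draws thus hold counting error only, and a coverage near 95% was built in. They do not cover other differences between libraries or in the makeup of a class. In astrocyte-like cells, TBI-GFP against control, 14205 genes entered the step, the interval of unchanged genes covered the true value for 95.7%, and 87.1% of genes set to a 2-fold change were recovered in the right direction. In microglia-like cells, TBI-ND1 against TBI-GFP, 13099 genes entered the step, and the same shares were 95.6% and 87.1%. All genes set to a 4-fold change were recovered (100%). Of genes set to a 1.5-fold change, 85.3% and 83.8% were recovered in astrocyte-like cells and 77.6% and 71.2% in microglia-like cells, for TBI-GFP against control and TBI-ND1 against TBI-GFP. Of 40 unchanged random lists per comparison, 1 to 3 fell outside the middle 95% of random lists.

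Alternatives covered the cell filter, the mitochondrial limit, doublets, joint clustering, Leiden resolutions of 0.5 and 2, edgeR 4.0.16 TMM factors in R 4.3.3, totals without mitochondrial and ribosomal protein genes, the minimum of UMIs per gene, the mean of per-cell CPM and thinning to 1000 UMIs per cell. A further 6 were added after the data were examined: a common floor of 2000 UMIs, a doublet score limit of 0.15 and 4 other makeups of the astrocyte or microglia class. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.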

Results

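Brain cells of 3 mouse libraries were profiled by single-cell RNA sequencing: control, TBI-GFP and TBI-ND1. The labels describe a NeuroD1 gene therapy of astrocytes after traumatic brain injury. By the labels, TBI-GFP against control differs by the injury with the reporter vector, and TBI-ND1 against TBI-GFP by NeuroD1. Each comparison also takes in any other difference between its libraries, such as the reporter level or the cell classes captured. The counts gave no check of the NeuroD1 label, as given below. The control library held 38246 barcodes and 141582012 UMIs, TBI-GFP held 40310 barcodes and 136435446 UMIs, and TBI-ND1 held 24842 barcodes and 122214642 UMIs. The median barcode held 2943 UMIs in control, 2709 UMIs in TBI-GFP and 3611 UMIs in TBI-ND1. The smallest barcode held 1750, 589 and 1982 UMIs in the same order, and barcodes under 2000 UMIs in shared genes were 13.6% of control, 38.1% of TBI-GFP and 4.00% of TBI-ND1. After filtering, 38173, 40172 and 24669 cells were kept. There were no replicates: each group is 1 library, so every difference given here is one between libraries.

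Astrocyte-like cells were 13% of kept cells in control (95% interval 12.6 to 13.3), 16.0% in TBI-GFP (15.6 to 16.3) and 7.04% in TBI-ND1 (6.73 to 7.37). Microglia-like cells were 7.55% (7.29 to 7.82), 8.78% (8.50 to 9.06) and 6.34% (6.04 to 6.66) in the same order. Oligodendrocyte-like cells, the myelin-forming class, were 21.2%, 29.0% and 38.1%. Neuron-like cells were 2.73%, 4.36% and 4.37%, and endothelial-like cells were 8.12%, 11.6% and 9.19%. Monocyte/macrophage-like cells were 4.34%, 2.15% and 1.99%. The cells under this name may differ between libraries, so these shares may not compare like cells. The MHC class II list in this class had a median log2 ratio of 6.08 in TBI-GFP against control. In TBI-ND1 against TBI-GFP it stood at −2.90. Clusters named neutrophil-like, T or NK lymphocyte-like and neuroblast-like were found in both TBI libraries, at 1.54%, 0.540% and 1.87% of TBI-GFP and at 0.543%, 0.470% and 1.76% of TBI-ND1. No control cluster took those names, but an unnamed control cluster of 321 cells was led by H2-Aa, Cd74 and the neutrophil genes S100a8 and S100a9, and another of 358 cells by Top2a and Sox11. Choroid plexus epithelial-like cells made up 4.27% of TBI-ND1 only, with a median of 16589 UMIs per cell.

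The lower floor of UMIs in TBI-GFP bears on these shares, since its astrocyte-like cells had a median of 1474 UMIs against 2529 in control and 3233 in TBI-ND1. Among cells with at least 2000 UMIs, astrocyte-like cells were 12.1%, 9.48% and 6.92%, so that the share in TBI-GFP was then lower than in control. Microglia-like cells were 6.31%, 6.49% and 5.83% at that floor. Doublet-like clusters, set apart by a rule chosen after the data were examined, held 23.3% of control, 3.70% of TBI-GFP and 4.44% of TBI-ND1. In control these included 3 clusters of microglia type, with 1265, 936 and 1161 cells, and with all doublet-like clusters kept the microglia share of TBI-GFP was 0.643 times that of control. Unnamed clusters held 11.2%, 11.6% and 14.8%, among them a cluster led by Spp1 with 1809 cells in TBI-GFP and 1239 cells in TBI-ND1. With the Spp1-led cells counted as microglia, the share of TBI-GFP was 1.76 times that of control.

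**Figure D1:**
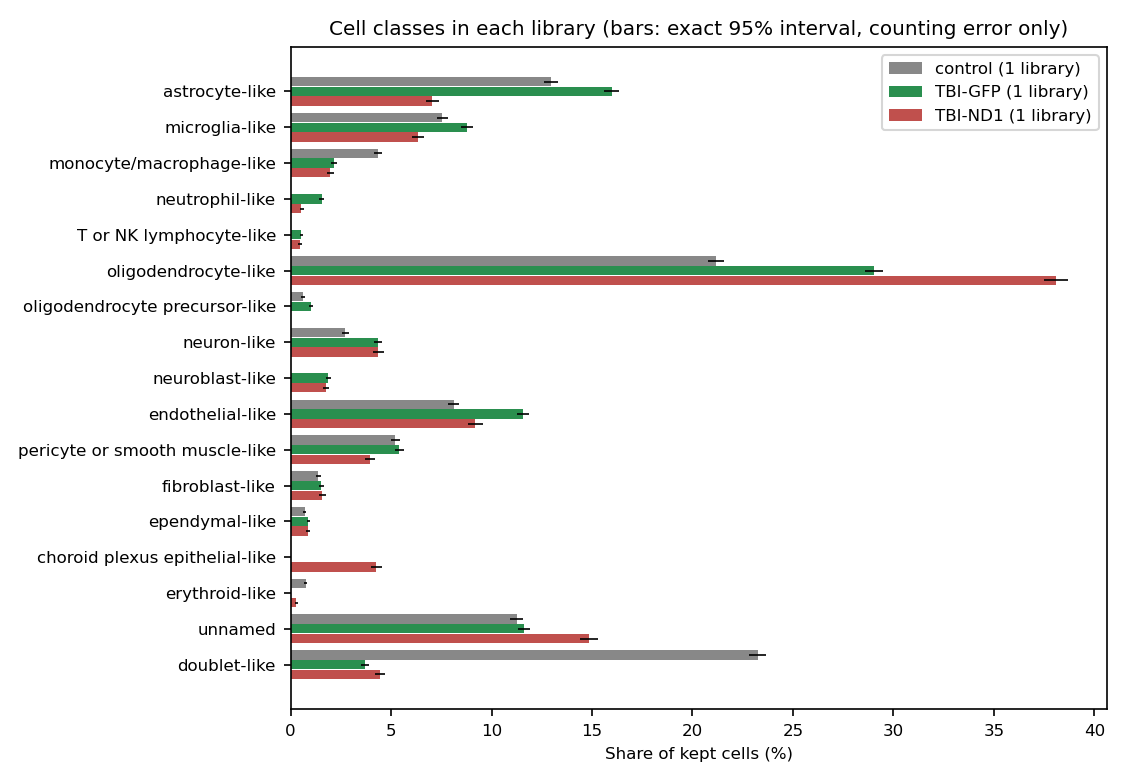
Share of kept cells (percent, horizontal axis) in each cell class, 1 bar per library, with exact 95% intervals for counting error. Astrocyte-like cells were 13% of control, 16.0% of TBI-GFP and 7.04% of TBI-ND1.

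Neurod1, the gene for the proneural transcription factor delivered in the study, was listed at 0 UMIs in every class of all 3 libraries. Neuron-like cells were among them, so the gene gave no check of the labels. The ND1 feature of the TBI gene tables had 0 UMIs in TBI-GFP and 1 UMI in TBI-ND1, in an astrocyte-like cell (0.148 CPM, 95% interval 0.00375 to 0.826).

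The GFP reporter was present in both TBI libraries and was highest in astrocyte-like cells. In TBI-GFP it reached 1171 CPM there (1154 to 1189), with a UMI in 20.1% of astrocyte-like cells. In TBI-ND1 it reached 88.9 CPM (82.0 to 96.4), with a UMI in 10.9% of cells. It was lower in the other classes of both libraries, and how much of it there was background was not tested: microglia-like cells, at a median of 1900 UMIs, held 30.1 CPM and a UMI in 3.83% of cells in TBI-GFP, and at a median of 2486 UMIs they held 2.75 CPM and a UMI in 0.511% of cells in TBI-ND1. Oligodendrocyte-like cells, at a median of 3514 UMIs, held 109 CPM and a UMI in 11.7% of cells in TBI-GFP, and 4.70 CPM in TBI-ND1. Ependymal-like cells of TBI-GFP, at a median of 2798 UMIs, held 248 CPM and a UMI in 15.8% of cells. Neuron-like cells held 58.3 CPM in TBI-GFP, within the range of the other classes. In TBI-ND1 they held 9.88 CPM (7.12 to 13.4), against 4.70 CPM (4.01 to 5.49) in oligodendrocyte-like cells, 7.64 CPM (3.50 to 14.5) in ependymal-like cells and 9.10 CPM (7.78 to 10.6) in unnamed clusters, and the last 2 intervals overlap that of neuron-like cells.

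The astrocyte class was made of different clusters in the 3 libraries. Control had a single cluster led by Aldoc. TBI-GFP had cluster 5 led by Gpc5 (2231 cells), cluster 6 rich in Gfap and Thbs4 (2546 cells) and cluster 13 led by Aldoc (1640 cells), with GFP at 375, 1489 and 1221 CPM. TBI-ND1 had cluster 13 led by Aldoc (863 cells), cluster 15 led by Gpc5 (508 cells) and cluster 17 led by Gal (366 cells), with GFP at 3.64, 14.4 and 431 CPM. Without cluster 17, GFP in the class stood at 7.89 CPM.

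**Figure D2:**
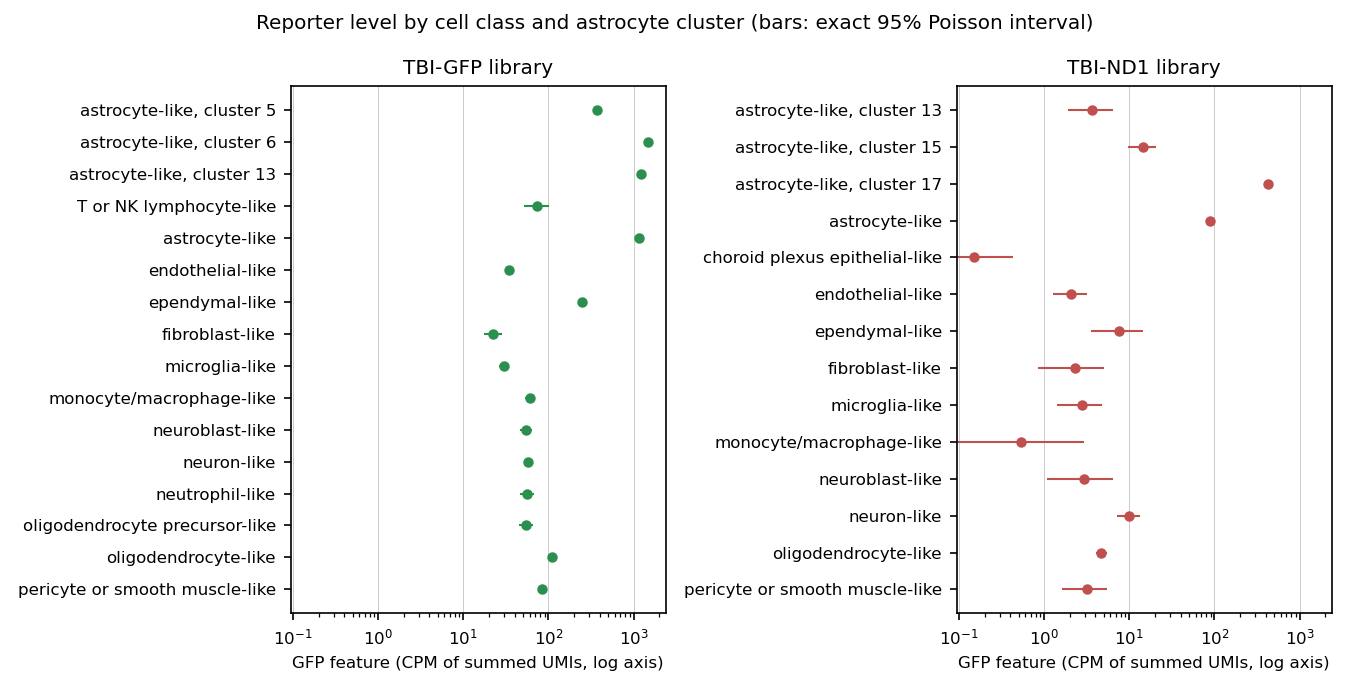
GFP level (CPM of summed UMIs, log axis) by cell class and by astrocyte cluster in TBI-GFP and TBI-ND1, with exact 95% Poisson intervals. Cluster 17 held 431 CPM in TBI-ND1, against 3.64 CPM in cluster 13 of that library.

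Astrocyte-like cells of TBI-GFP carried the genes of reactive astrocytes at higher levels than those of control. Gfap, the intermediate filament gene of reactive astrocytes, stood at 1211 CPM in TBI-GFP and 153 CPM in control (log2 ratio 2.98, 95% interval 2.92 to 3.05). Oligodendrocyte RNA in the class was higher as well: Mbp, a myelin gene, stood at 2727 CPM in TBI-GFP and 371 CPM in control, and Mog at 603 and 110 CPM, while over all kept cells Mbp stood at 5152 and 3014 CPM. The pan-reactive list had a median log2 ratio of 2.06 (1.94 to 2.14), above all random lists (percentile 100), with 11 of 13 measured genes at least 1.5-fold higher and 0 lower. Lcn2, an iron-carrier protein of inflammation, was higher by 5.37 and the chemokine gene Cxcl10 by 4.12. Lcn2 stood at 22.6 CPM and Cxcl10 at 12.98 CPM in these cells, against 45.17 and 13.25 CPM over all kept TBI-GFP cells, and Lcn2 over all kept control cells stood at 4.69 CPM. The A1 list had a median of 1.46 (1.22 to 1.63; percentile 100), with 7 of 11 genes higher and 3 lower, led by Gbp2 (2.99) and the complement inhibitor Serping1 (2.79). The A2 list had a median of 3.06 (2.28 to 3.61; percentile 100), with 9 of 10 genes higher. Of these, Tgm1 was at 0 UMIs in control and at least 19.6-fold higher against a floor of 3 counts, Cd109 was higher by 4.58 (3.38 to 7.28, with 3 UMIs in control) and the prostaglandin synthase gene Ptgs2 by 3.61. With only the Aldoc-led cluster of each library, which leaves out the Gfap-rich cluster 6, the pan-reactive median was 0.70 and the A2 median was −0.11.

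Transcripts of the homeostatic astrocyte list were lower in TBI-GFP, in a class whose Mbp level was higher, as given above. The list had a median of −0.90 (−0.92 to −0.88; percentile 0.02), with 14 of 18 genes at least 1.5-fold lower and 0 higher. The protease gene Htra1 stood at −1.42 and Aldoc at −1.23. The same list had a median of −1.46 over the other classes, most of which are not expected to make these transcripts, and with only the Aldoc-led clusters the astrocyte median was −0.18. Cholesterol synthesis genes had a median of −0.67 (−0.72 to −0.64; percentile 0.08), with 11 of 15 lower, among them Msmo1 (−1.40). Nuclear oxidative phosphorylation genes had a median of −0.43 (−0.48 to −0.40; percentile 0.01), with 26 of 81 lower and 5 higher. The members with the largest ratios went both ways, with Atp5o at 2.31, Cox8b at 1.28 and Cox7b at −1.23. Atp5o stood at 36.5 and 232 CPM over all kept cells of control and TBI-GFP, and the control table lists a further Atp5o identifier that the TBI tables lack. Cox8b stood at 0.821 CPM in control and 2.08 CPM in TBI-GFP astrocyte-like cells. Over the other classes the median of that list was −0.15, from −0.65 in neuron-like to −0.01 in oligodendrocyte-like cells, and with only the Aldoc-led clusters the astrocyte median was −0.22. The mitochondrially encoded genes stood at 0.45 (0.44 to 0.52; percentile 96.9), with mt-Cytb at 1.25. Glycolysis genes had a median of −0.55 (−0.74 to −0.50; percentile 0.215), with 9 of 19 lower and 2 higher, among them the lactate transporter gene Slc16a3 at 1.56, the phosphofructokinase gene Pfkm at −1.53 and Pgk1 at −1.38.

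Interferon response genes were higher in TBI-GFP astrocyte-like cells, with a median of 1.36 (0.98 to 1.51; percentile 100) and 15 of 23 genes higher, led by Ifit2 (3.0) and Ifit1 (2.88). MHC class I genes, which present peptides to T cells, had a median of 1.12 (0.61 to 1.40; percentile 100), with 8 of 13 higher, led by H2-Q6 (1.78) and the immunoproteasome gene Psmb9 (1.64). Over all kept TBI-GFP cells Ifit2 stood at 34.8 CPM, H2-Q6 at 11.6 CPM and Psmb9 at 34.7 CPM, above the 20.8, 1.80 and 8.47 CPM of astrocyte-like cells. Immediate-early genes, which also respond to tissue dissociation, had a median of 1.19 (1.12 to 1.26; percentile 100), with 14 of 18 higher, led by Fos (2.21) and Egr1 (2.13). The interferon, MHC class I and immediate-early medians were 0.74, 0.74 and 0.24 in the Aldoc-led clusters alone. Over the other classes the medians of these lists were 0.58, 0.67 and 0.68. The disease-associated microglia list stood at 0.54 (percentile 99.5) and the homeostatic microglia list at −0.58 (percentile 0.05). The complement list had a median of −0.28 with an interval of −0.34 to 0.20, although its member C3 was higher by 7.20 (5.71 to 13.5, with 1 UMI in control) and C4b by 3.51. The neurogenic list had a median of −0.01 (percentile 19.9), with Neurog2 at 4.23 (2.62 to 10.5, with 1 UMI in control) and Insm1 at 3.56. Medians within the middle 95% of random lists were also those of hypoxia response (0.26), antioxidant (−0.23), cytokine and NF-kB (0.23), MHC class II (0.67), phagocytosis (−0.07), matrix and scar (−0.25), synapse support (−0.30), proliferation (0.64) and ribosomal protein genes (−0.12).

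The 10 genes highest in TBI-GFP astrocyte-like cells by ratio were Mrps6, Fam173a, Slc38a1, Thbs4, Metrn, Hdhd2, Fxyd6, C4b, Ass1 and Gfap. The amino acid transporter gene Slc38a1 was higher by 4.73 (4.33 to 5.22), the thrombospondin gene Thbs4 by 4.6 (4.28 to 4.96), Fxyd6 by 3.85 (3.52 to 4.24) and the arginine synthesis gene Ass1 by 3.20 (2.88 to 3.57). Slc38a1, Fxyd6 and Ass1 stood at medians of 0.59, 0.29 and 0.64 over the other classes, and Fxyd6 stood at −0.98 in the Aldoc-led clusters alone. Gfap, Thbs4 and C4b stood at medians of 1.31, 1.41 and 4.30 over the other classes, the last above its astrocyte value of 3.51. Mrps6 had 1086 UMIs against 0 in control, at least 367-fold higher, Fam173a was higher by 8.69 (7.55 to 11.4, with 3 UMIs in control), Metrn by 4.45 and Hdhd2 by 4.20, and these 4 genes had medians of 8.27, 8.15, 4.25 and 4.37 over the other classes. The 10 lowest were Efcab8 (−5.72), Rabgef1 (−4.33), Cfap46 (−3.01), Igfbp2 (−2.75), Hsd17b4 (−2.58), Gpam (−2.54), Fcrla (−2.51), Fads2 (−2.33), Sult1a1 (−2.27) and Tubb2a (−2.11). Of the genes higher, 7 of 10 were at least 2-fold higher in at least 50% of the other classes, and of the genes lower, 8 of 10 were at least 2-fold lower there. The gene table of control differs from that of TBI-GFP. The median over all genes in this comparison was 0.12 and moved to 0.00 with TMM factors.

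**Figure D3:**
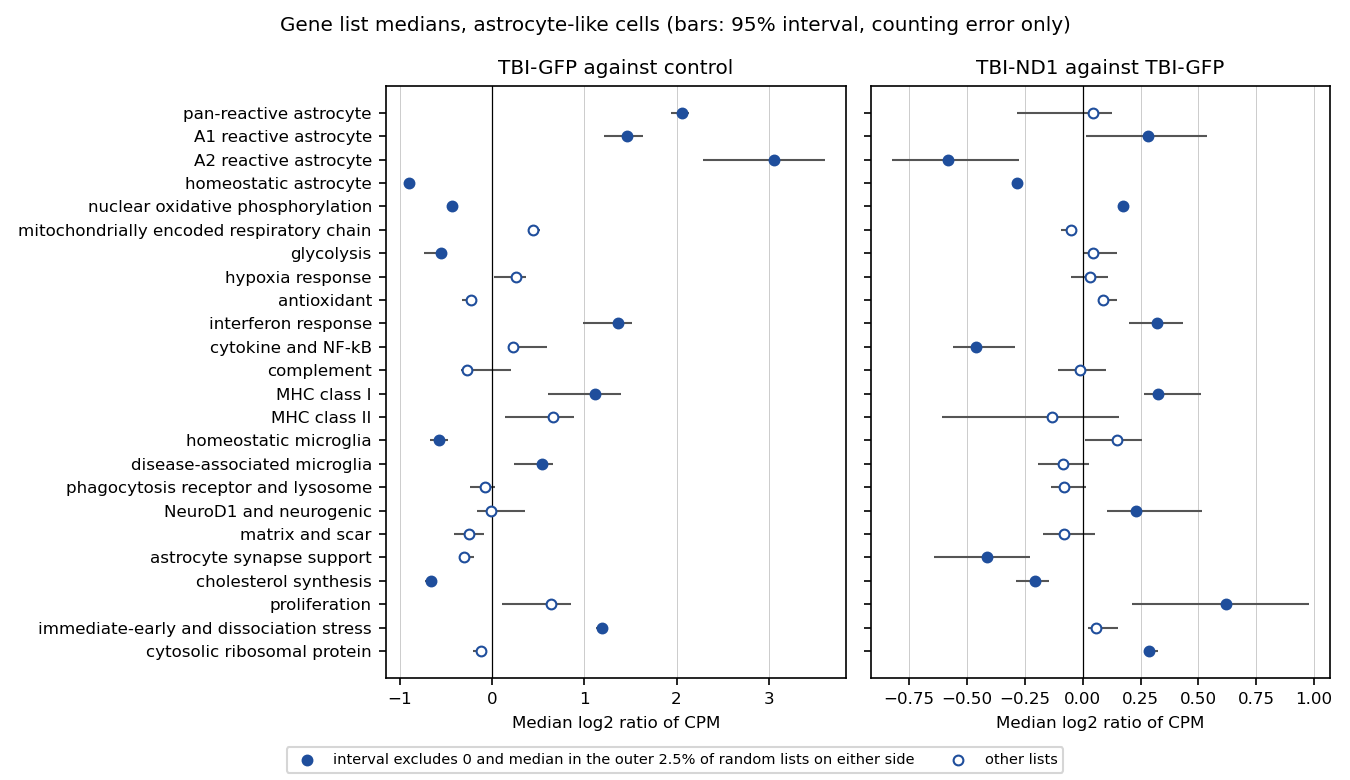
Median log2 ratio of CPM (horizontal axis) of each gene list in astrocyte-like cells, for TBI-GFP against control and TBI-ND1 against TBI-GFP, with 95% intervals for counting error. The pan-reactive list stood at 2.06 in the first comparison and at 0.04 in the second.

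Between TBI-ND1 and TBI-GFP astrocyte-like cells, Gal had the largest ratio among the genes named by rule. RNA of other cell types in the class differed unevenly. In TBI-ND1 and TBI-GFP, Mbp was at 2961 and 2727 CPM and the endothelial gene Cldn5 at 23.1 and 28.2 CPM. The microglia gene Cx3cr1 was at 28.2 and 24.9 CPM. The haemoglobin gene Hba-a1 was higher in TBI-ND1, at 1368 and 434 CPM. So were the choroid plexus genes Kcnj13, at 32.8 and 0.208 CPM, and Ttr, given below. Gal, the gene of the neuropeptide galanin, stood at 2776 CPM in TBI-ND1 and 27.4 CPM in TBI-GFP (log2 ratio 6.66, 6.52 to 6.81). Sct, the gene of the peptide hormone secretin, was higher by 6.0 (5.63 to 6.45), the matrix gene Mfap4 by 5.04 (4.50 to 5.75) and Cpne9 by 4.27 (3.98 to 4.59). Cacng5, Cadm3, Fndc5, the cell cycle gene Ccnd1, Serping1 and Olfm1 were higher by 2.92, 2.74, 2.27, 1.64, 1.56 and 1.5. Gal is a leading gene of cluster 17, which held 366 of the 1737 astrocyte-like cells of TBI-ND1. A cluster found in a single library may reflect that library rather than a cell type. With only the Aldoc-led clusters, Gal stood at −0.54, Cpne9 at −1.63, Cacng5 at −0.79, Fndc5 at −0.71 and Olfm1 at −0.18, while Sct stood at 1.05 and Mfap4 at 1.75. Gal, Sct and Cpne9 were also higher in other classes of TBI-ND1, by medians of 4.47, 3.78 and 3.18.

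The 10 lowest genes in TBI-ND1 astrocyte-like cells were Kcnd2 (−1.84), Cmss1 (−1.55), Lama2 (−1.40), Fry (−1.35), Adgrb3 (−1.34), Park2 (−1.32), Hdac9 (−1.31), Thbs4 (−1.30), Klf12 (−1.27) and Gpc5 (−1.26). The potassium channel gene Kcnd2 and the glypican gene Gpc5 are long genes, and the Gpc5-led clusters held 2231 of 6417 astrocyte-like cells in TBI-GFP and 508 of 1737 in TBI-ND1. Without these clusters, Adgrb3 stood at 0.09, Klf12 at 0.08 and Gpc5 at 0.36. Thbs4 stood at 1.51 and Park2 at 0.03 in the Aldoc-led clusters alone.

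The pan-reactive list did not differ detectably between TBI-ND1 and TBI-GFP astrocyte-like cells, at 0.04 (−0.28 to 0.12; percentile 61.8). Its members Vim (0.73), Cp (0.72) and Gfap (0.71) were higher, while Lcn2 was lower (−0.69). That median was 1.16 in the Aldoc-led clusters alone. The A2 list had a median of −0.58 (−0.83 to −0.27; percentile 0.05), with 5 of 10 genes lower and 0 higher, led by Tgm1 (−2.20) and the pentraxin gene Ptx3 (−1.34). In the Aldoc-led clusters alone it stood at 1.47, with Ptx3 at 1.55 and Lcn2 of the pan-reactive list at 0.90. The A1 list had a median of 0.28 (0.01 to 0.54; percentile 99.4), led by Serping1 (1.56) and H2-D1 (0.89), and stood at −0.21 with the mean of per-cell CPM. Cytokine and NF-kB genes had a median of −0.46 (−0.56 to −0.29; percentile 0.02), with 11 of 24 lower and 0 higher, led by the chemokine gene Cxcl2 (−1.74) and the interleukin gene Il1b (−1.49). Cxcl2 stood at 1.93 and 6.87 CPM and Il1b at 0.741 and 2.43 CPM in these cells, against 77.0 and 48.5 CPM over all kept TBI-GFP cells and 551 and 481 CPM in its Spp1-led cells. That median was −0.10 without the Gpc5-led clusters and 0.01 with only the Aldoc-led clusters.

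Interferon response genes were higher in TBI-ND1 astrocyte-like cells, with a median of 0.32 (0.20 to 0.43; percentile 100), 6 of 23 higher and 0 lower, led by Bst2 (1.0) and Usp18 (0.98, and −0.04 with cells thinned to 1000 UMIs). Bst2 stood at 41.1 CPM in TBI-ND1 and 20.5 CPM in TBI-GFP astrocyte-like cells, and at 137 and 72.2 CPM over all kept cells. MHC class I genes had a median of 0.32 (0.27 to 0.51; percentile 99.7), led by H2-Q7 (1.44). Nuclear oxidative phosphorylation genes had a median of 0.17 (0.16 to 0.20; percentile 99.8), with 3 of 81 higher and 2 lower, and the largest ratios were those of Cox8b (2.95) and Cox6a2 (−2.02). Cox8b stood at 16.5 CPM in TBI-ND1 astrocyte-like cells and at 49.7 CPM over all kept TBI-ND1 cells, and the choroid plexus gene Kcnj13 stood at 32.8 and 399 CPM in the same order, against 0.208 CPM in TBI-GFP astrocyte-like cells. Cox6a2 stood at 0.297 CPM in TBI-ND1 and 1.74 CPM in TBI-GFP astrocyte-like cells, and at 166 CPM in Spp1-led TBI-GFP cells. The median of the list was 0.00 in the Aldoc-led clusters alone. The mitochondrially encoded genes stood at −0.05. The homeostatic astrocyte list had a median of −0.28 (−0.31 to −0.26; percentile 0.02), led by the amino acid transporter gene Slc7a10 (−0.81) and the connexin gene Gjb6 (−0.58). Synapse support genes had a median of −0.41 (−0.64 to −0.23; percentile 0.01), led by Thbs4 (−1.30), Gpc6 (−1.04) and Nlgn1 (−1.04). Without the Gpc5-led clusters these medians were 0.11 and 0.29, with Gpc6 at 0.43 and Nlgn1 at 0.26.

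The neurogenic list had a median of 0.23 in TBI-ND1 against TBI-GFP (0.10 to 0.52; percentile 97.9), with 6 of 14 measured genes higher and 1 lower. Neurod2 was higher by 2.62, at 3.26 CPM against 0.486 CPM, the neuronal gene Rbfox3 was higher by 1.78, and Neurog2 was lower (−1.53). Proliferation genes had a median of 0.62 (0.21 to 0.98; percentile 99.9), with 7 of 13 higher and 1 lower, led by Ube2c (1.85) and Top2a (1.56), at 3.11 and 2.52 CPM in TBI-ND1, against 20.3 and 20.1 CPM over all kept cells of that library. Mki67 stood at 0.741 CPM in TBI-ND1 and 1.53 CPM in TBI-GFP. Ribosomal protein genes stood at 0.29 (percentile 100) and cholesterol synthesis genes at −0.21 (percentile 0.47). The medians of glycolysis (0.04), hypoxia response (0.03), antioxidant (0.09), complement (−0.01), MHC class II (−0.13), homeostatic microglia (0.15), disease-associated microglia (−0.09), phagocytosis (−0.08), matrix and scar (−0.08) and immediate-early genes (0.06) lay within the middle 95% of random lists.

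Microglia-like cells of TBI-GFP carried antigen presentation and interferon genes at higher levels than those of control. The class was cluster 17 in control, cluster 9 in TBI-GFP and cluster 2 in TBI-ND1. MHC class II genes had a median of 2.08 (1.48 to 2.46; percentile 100), with 7 of 7 higher, led by H2-Aa (2.90), the invariant chain gene Cd74 (2.45, 2.36 to 2.55) and H2-Ab1 (2.31). H2-Aa stood at 103 CPM and H2-Ab1 at 144 CPM in these cells, against 183 and 147 CPM over all kept TBI-GFP cells and 265 and 261 CPM in its Spp1-led cells. Interferon response genes had a median of 1.42 (1.24 to 1.65; percentile 100), with 20 of 22 higher, led by Oasl2 (2.65), Ifi27l2a (2.64) and Rtp4 (2.51), at 16.6, 27.5 and 29.6 CPM in these cells and at 16.1, 36.2 and 30.8 CPM over all kept TBI-GFP cells. MHC class I genes had a median of 0.64 (0.59 to 0.73; percentile 100), with 7 of 14 higher, among them the class I regulator gene Nlrc5 (4.31, 3.11 to 7.01, with 3 UMIs in control) and H2-Q7 (2.30). The disease-associated microglia list had a median of 0.63 (0.54 to 0.77; percentile 100), with 12 of 20 higher and 1 lower. The lipoprotein gene Apoe was higher by 2.75, Spp1 by 2.61, and Gpnmb, at 0 UMIs in control, was at least 11.7-fold higher. Gpnmb stood at 4.69 CPM and Spp1 at 53.8 CPM in these cells, below the 108 and 414 CPM over all kept TBI-GFP cells and the 1266 and 4699 CPM of its Spp1-led cells, and Apoe stood at 10056 CPM against 14573 CPM over all kept cells. Oligodendrocyte RNA was also higher in the class, with Mbp at 1348 CPM in TBI-GFP and 411 CPM in control. With the Spp1-led cells added, the median of the disease-associated list was 2.66 and that of the interferon list was 2.21. Under joint clustering of the 3 libraries the interferon median was 0.76. Part of these rises was shared with other classes. Over those classes the interferon list had a median of 0.58, from 0.43 to 1.61, and MHC class I genes a median of 0.67. MHC class II genes stood at 0.39 there, from −0.99 to 6.08. The disease-associated list stood at 0.37 there, with its highest value, 0.84, in neuron-like cells.

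Homeostatic microglia genes differed little between TBI-GFP and control, at −0.08 (−0.11 to −0.05; percentile 25.1). The cytokine and NF-kB list stood at −0.17 (−0.31 to −0.07; percentile 2.84), with 8 of 24 lower and 3 higher. The tumour necrosis factor gene Tnf was lower (−2.0, −2.14 to −1.86) and Cxcl1 higher (2.08). Phagocytosis genes stood at 0.28 (percentile 99.1), immediate-early genes at 0.27 (percentile 99.5) with Hspa1a at 1.59, and oxidative phosphorylation genes at −0.13 (percentile 0.48). Astrocyte RNA in microglia-like cells was lower in TBI-GFP, with the homeostatic astrocyte list at −1.59 and Aldoc at −2.59. The 10 genes highest by ratio were Rnaset2a, Wdr89, Capn3, Taf6l, Fgl2, Coro1b, Hcar2, Cd74, Ogfrl1 and Gadd45g, and 10 of 10 were at least 2-fold higher in at least 50% of the other classes. Among them the niacin receptor gene Hcar2 was higher by 2.86 (2.61 to 3.13) and Fgl2 by 3.38 (3.09 to 3.72). Rnaset2a, at 0 UMIs in control, was at least 1772-fold higher, and its median over the other classes was 9.78. The 10 lowest were Tecpr2, Ftl1, Cyb561a3, Cnot6, Tnf, Rcan1, Ctsd, C5ar2, Hmgb2 and Gpr165, from −4.74 to −1.38, and 7 of 10 were at least 2-fold lower in at least 50% of the other classes.

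**Figure D4:**
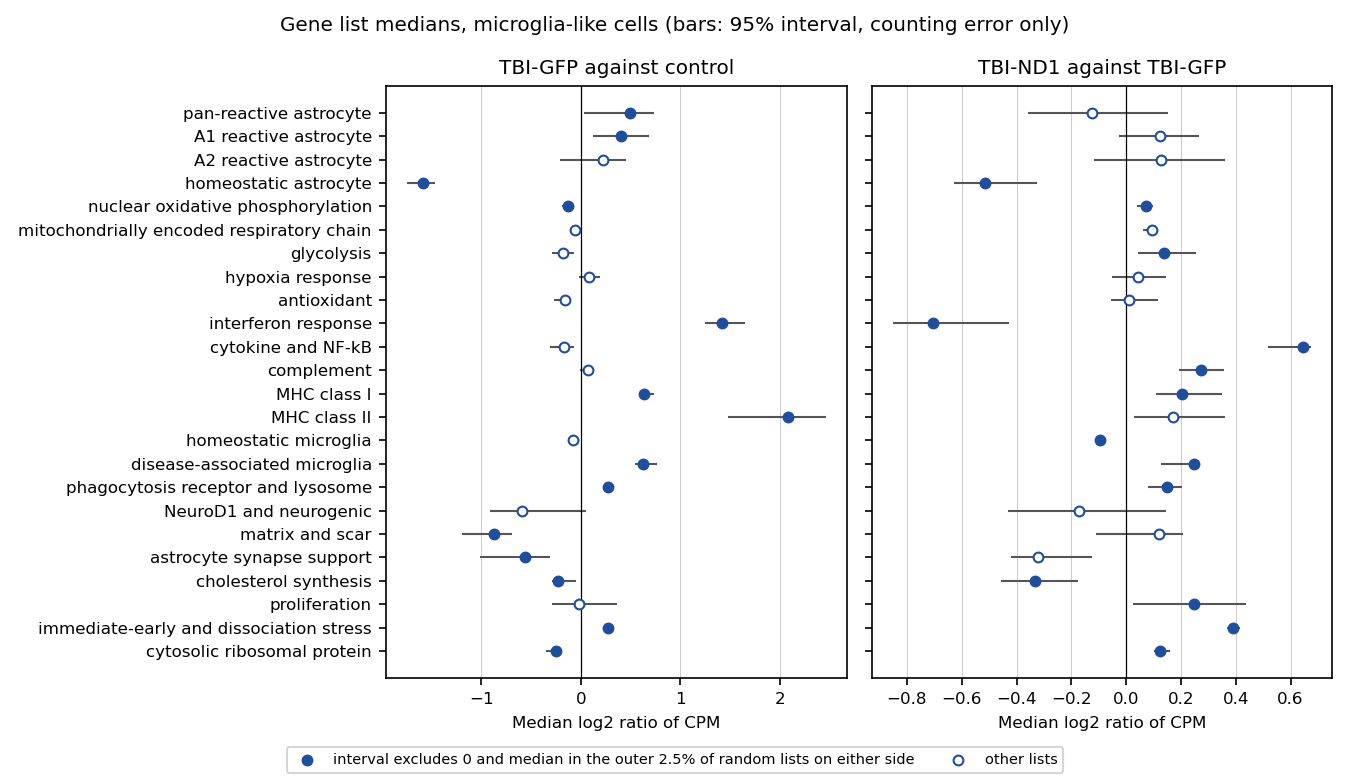
Median log2 ratio of CPM (horizontal axis) of each gene list in microglia-like cells, for TBI-GFP against control and TBI-ND1 against TBI-GFP, with 95% intervals for counting error. The interferon list stood at 1.42 in the first comparison and at −0.71 in the second.

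Microglia-like cells of TBI-ND1 held more cytokine and fewer interferon transcripts than those of TBI-GFP. They also held less oligodendrocyte RNA, with Mbp at 495 CPM in TBI-ND1 and 1348 CPM in TBI-GFP and Cldn11 at 242 and 755 CPM. The cytokine and NF-kB list had a median of 0.65 (0.52 to 0.68; percentile 100), with 13 of 24 higher and 0 lower. Cxcl2 was higher by 2.22 (2.02 to 2.43), Nfkbiz by 1.33 (1.23 to 1.43), Tnfaip3 by 1.18 (1.06 to 1.30) and Tnf by 1.14 (0.98 to 1.31). The prostaglandin synthase gene Ptgs2 (1.80), Nr4a1 (1.01), Zc3h12a (1.0), Gdf15 (1.0), Csf1 (0.97) and Maff (0.96) completed the 10 highest genes. None of them (0 of 10) was 2-fold higher in at least 50% of the other classes, but Zc3h12a, Gdf15, Csf1 and Maff were under 2-fold in microglia-like cells too. Gdf15 stood at a median of 0.84 over the other classes, near its value in microglia-like cells. The medians of the remaining genes there ran from −0.30 (Maff) to −0.0036 (Tnfaip3). The interferon list had a median of −0.71 (−0.85 to −0.43; percentile 0), with 13 of 23 lower and 1 higher, led by Ifit3b (−2.25), Ifit3 (−1.57) and Ifit1 (−1.56). The cytokine median was −0.07 under joint clustering and −0.07 with the Spp1-led cells added, and the interferon median was 0.07 under joint clustering. With the Spp1-led cells added, Cxcl2 stood at −0.21, Nfkbiz at −0.05, Tnfaip3 at −0.03, Tnf at −0.36, Nr4a1 at −0.01 and Maff at −0.22, and under joint clustering Tnf stood at −0.10 and Maff at −0.27. The median over all genes was −0.10 in this comparison and 0.00 with TMM factors.

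Immediate-early genes were also higher in TBI-ND1 microglia-like cells, at 0.39 (0.37 to 0.41; percentile 100), with Nr4a1 at 1.01 and Atf3 at 0.84, and at −0.05 with the Spp1-led cells added. The disease-associated microglia list stood at 0.25 (0.13 to 0.26; percentile 100), with 3 of 21 higher and 2 lower, among them Csf1 (0.97), Fabp5 (−0.91) and Clec7a (0.80). With doublet-like clusters kept it stood at −0.25, with Fabp5 at 0.30 and Clec7a at −0.70. Fabp5 stood at 0.09 under joint clustering and 0.10 with the Spp1-led cells added. Complement genes stood at 0.27 (percentile 99.9), MHC class I genes at 0.20 (percentile 100; −0.04 with doublet-like clusters kept) with H2-Q7 at 1.37, and MHC class II genes at 0.17 (percentile 97.3) with Cd74 at 0.73. Homeostatic microglia genes stood at −0.09 (−0.11 to −0.07) and at 0.01 with TMM factors and 0.08 at 2000 UMIs or more per cell. Among the lowest genes were Slc8a1, Fgl2, Mir99ahg, Zufsp, Csmd3, Zeb1, Nav2, Ipo11 and Tbc1d5, from −0.77 to −0.53, with Fgl2 at 0.04 under joint clustering.

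In TBI-ND1 against control, astrocyte-like cells showed the pan-reactive list at 2.06 (1.71 to 2.21), the interferon list at 1.64 (1.33 to 1.83), the homeostatic list at −1.24 (−1.27 to −1.21) and nuclear oxidative phosphorylation at −0.30 (−0.33 to −0.25). The neurogenic list stood at 1.17 (0.71 to 1.28; percentile 100), with 8 of 14 measured genes higher and 1 lower, while Mbp in the class stood at 2961 CPM in TBI-ND1 and 371 CPM in control. The neurogenic median was 0.46 without the Gpc5-led clusters, 0.52 without the Gal-led cluster and 0.28 in the Aldoc-led clusters alone. Its member Elavl3 stood at 166 and 31.9 CPM in astrocyte-like cells of TBI-ND1 and control, and at 146 CPM in those of TBI-GFP. In microglia-like cells the interferon list stood at 0.77 (0.61 to 0.92), MHC class II at 2.06 (1.90 to 2.46), the disease-associated list at 0.90 (0.69 to 0.93) and the cytokine and NF-kB list at 0.19 (0.10 to 0.33), the last at −0.11 under joint clustering.

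The authors' deposited table of mean values holds 25154 genes and 1 column per group. Means of values scaled to 10000 per cell were recomputed here from all barcodes. Among genes with a deposited value of at least 0.05, 99.5% of 12110 genes in TBI-GFP, 99.5% of 11789 genes in TBI-ND1 and 99.7% of 11528 genes in control lay within 1.5-fold of the deposited value. In the authors' deposited table GFP stands at 2.48 in TBI-GFP, 0.0947 in TBI-ND1 and 0 in control, and Gal at 0.107, 2.19 and 0.000488. The control gene table lacks a GFP feature, so the GFP value of 0 there is not a measured absence. The authors' deposited table gives Gfap at 1.61, 1.31 and 0.417 and Aqp4, a water channel gene of astrocytes, at 1.94, 0.839 and 2.68, in the same order.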

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

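All tests of explanations in this part were chosen after the results were seen. In TBI-ND1 against TBI-GFP, 2 gene lists lay in opposite directions in astrocyte-like and microglia-like cells, and the difference between the classes was not tested. The cytokine and NF-kB list had a median of −0.46 in astrocyte-like cells and 0.65 in microglia-like cells. The interferon response list had a median of 0.32 in astrocyte-like cells and −0.71 in microglia-like cells. These directions depended on which cells count in a class. The astrocyte cytokine median was 0.0060 with only the Aldoc-led clusters. Under joint clustering the microglia medians were −0.069 for cytokine and 0.075 for interferon genes. Each value comes from 1 library per group.

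The higher cytokine and NF-kB genes in TBI-ND1 microglia-like cells, led by Cxcl2 and Nfkbiz, were weighed against 2 technical explanations. More dissociation stress in the whole TBI-ND1 library cannot be told apart from a change in microglia. The immediate-early list had a median of 0.0089 over the other classes, but their values ran from −0.63 in oligodendrocyte-like to 0.61 in neutrophil-like cells. The other classes also cannot speak to stress in microglia-like cells themselves, where that list was higher in TBI-ND1, as given above. A candidate explanation is which clusters count as microglia: with the Spp1-led cells of both TBI libraries added, the cytokine median was −0.074. An effect of NeuroD1 delivery on microglia was not tested apart from this and stays open.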

How the results depend on the processing

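Alternatives were planned before the data were examined, apart from 6 that were chosen after it: the floor of 2000 UMIs, the doublet score limit, and the 4 settings that leave out or add clusters by their leading gene. Log2 medians and ratios are given unless CPM or share is named, and the cause of a change was not tested except where a setting changes the cells of a class by its construction. The planned values per sub-library were not run, since the barcodes carry no label of sub-libraries.

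In astrocyte-like cells, the lower share in TBI-ND1 than in TBI-GFP kept its direction under every alternative run, while the higher share in TBI-GFP than in control did not. The higher pan-reactive list and the lower nuclear oxidative phosphorylation list of TBI-GFP against control kept their direction under every alternative run. So did the higher GFP level of TBI-GFP. In microglia-like cells, the higher interferon and disease-associated lists of TBI-GFP against control kept their direction under every alternative run. The cytokine and interferon differences between TBI-ND1 and TBI-GFP microglia-like cells did not.

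Across alternatives, 15 values of share ratios stayed within their counting interval, 19 moved and 6 changed direction. For the GFP level 11 stayed and 9 moved. For list medians that answer a comparison 97 stayed, 48 moved and 5 changed direction. Other list medians gave 1455, 537 and 18 values in the same order, and single named genes gave 1750, 509 and 30.

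With at least 1000 UMIs per cell, the share of astrocyte-like cells, TBI-GFP over control, was 0.996, and the share of astrocyte-like cells, TBI-ND1 over TBI-GFP, was 0.546. The astrocyte oxidative phosphorylation median was −0.38 in TBI-GFP against control and 0.14 in TBI-ND1 against TBI-GFP. With at least 200 genes and no other limit, these shares were 1.10 and 0.492, and the microglia share of TBI-GFP over control was 1.27. The GFP CPM in astrocyte-like cells of TBI-GFP was 1322, the pan-reactive median of TBI-GFP against control 2.16 and the astrocyte oxidative phosphorylation median of TBI-ND1 against TBI-GFP 0.14. In microglia-like cells the cholesterol median of TBI-GFP against control was 0.14, and in TBI-ND1 against TBI-GFP the medians were −0.062 for oxidative phosphorylation, −0.20 for interferon, 0.89 for cytokine and 0.48 for disease-associated genes.

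Under the floor of 2000 UMIs, the astrocyte shares were 0.781 (TBI-GFP over control) and 0.730 (TBI-ND1 over TBI-GFP), the microglia shares 1.03 and 0.898, and the GFP CPM in astrocyte-like cells of TBI-GFP 1075. The pan-reactive median of TBI-GFP against control was 2.23, the oxidative phosphorylation medians in astrocyte-like cells −0.39 and 0.10, and the astrocyte cytokine median of TBI-ND1 against TBI-GFP −0.13. In microglia-like cells of that comparison, oxidative phosphorylation stood at −0.0093, homeostatic genes at 0.078 and disease-associated genes at 0.12. Without cells above the doublet score limit of 0.15, the astrocyte shares were 1.09 and 0.465, the microglia share of TBI-GFP over control 1.09 and GFP in TBI-GFP astrocyte-like cells 1262 CPM. The medians were then 2.26 for pan-reactive and −0.39 for oxidative phosphorylation genes in astrocyte-like cells of TBI-GFP against control, and −0.65 (astrocyte) and 0.47 (microglia) for cytokine genes of TBI-ND1 against TBI-GFP.

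Under joint clustering, the shares of TBI-GFP over control were 0.946 (astrocyte) and 0.909 (microglia), GFP in TBI-GFP 1347 CPM and the pan-reactive median of TBI-GFP against control 2.33. The microglia interferon median of TBI-GFP against control was 0.76. For TBI-ND1 against TBI-GFP in microglia-like cells, interferon stood at 0.075, cytokine at −0.069, cholesterol at 0.024, Tnf at −0.10, Maff at −0.27, Fgl2 at 0.041 and Fabp5 at 0.085. The microglia cytokine median of TBI-ND1 against control was −0.11. At Leiden resolution 0.5, the astrocyte share of TBI-GFP over control was 1.17 and the microglia shares 1.89 (TBI-GFP over control) and 0.548 (TBI-ND1 over TBI-GFP). At resolution 2, the shares of TBI-GFP over control were 1.04 (astrocyte) and 1.29 (microglia).

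With doublet-like clusters kept, the microglia shares were 0.643 and 0.810. In microglia-like cells of TBI-GFP against control, pan-reactive genes stood at −0.11, interferon at 0.94 and disease-associated genes at 1.02. For TBI-ND1 against TBI-GFP they stood at −0.27 for interferon, 0.28 for cytokine, −0.035 for MHC class I, −0.25 for disease-associated and −0.093 for phagocytosis genes, with Fabp5 at 0.30 and Clec7a at −0.70. With the Spp1-led clusters added, the microglia shares were 1.76 and 0.856. In TBI-GFP against control, interferon stood at 2.21, disease-associated genes at 2.66 and ribosomal protein genes at 0.029, the last at 0.032 in TBI-ND1 against control. For TBI-ND1 against TBI-GFP, interferon stood at −0.15, cytokine at −0.074 and immediate-early genes at −0.045, with Cxcl2 at −0.21, Nfkbiz at −0.055, Tnfaip3 at −0.029, Tnf at −0.36, Nr4a1 at −0.0090, Maff at −0.22 and Fabp5 at 0.10.

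Without the Gpc5-led clusters, the astrocyte shares were 0.804 and 0.478, GFP 1382 CPM in TBI-GFP and 124 CPM in TBI-ND1, and the medians of TBI-GFP against control 2.36 (pan-reactive) and −0.35 (oxidative phosphorylation). In TBI-ND1 against TBI-GFP, pan-reactive stood at 0.19, homeostatic at 0.11, cytokine at −0.10 and synapse support at 0.29, with Adgrb3 at 0.090, Klf12 at 0.077, Gpc5 at 0.36, Gpc6 at 0.43 and Nlgn1 at 0.26. With the Aldoc-led clusters alone, GFP was 1221 CPM in TBI-GFP and 3.64 CPM in TBI-ND1. In TBI-GFP against control, pan-reactive stood at 0.70, A2 at −0.11, oxidative phosphorylation at −0.22 and Fxyd6 at −0.98. In TBI-ND1 against TBI-GFP, pan-reactive stood at 1.16, A2 at 1.47, oxidative phosphorylation at 0.0012 and cytokine at 0.0060, with Gal at −0.54, Cpne9 at −1.63, Cacng5 at −0.79, Fndc5 at −0.71, Olfm1 at −0.18, Park2 at 0.029, Thbs4 at 1.51, Ptx3 at 1.55 and Lcn2 at 0.90. Without the Gal-led cluster, GFP in TBI-ND1 was 7.89 CPM, and in TBI-ND1 against TBI-GFP oxidative phosphorylation stood at 0.10 and Fndc5 at −0.089.

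TMM factors gave −0.55 for oxidative phosphorylation in astrocyte-like cells of TBI-GFP against control, and in microglia-like cells of TBI-ND1 against TBI-GFP 0.76 for cytokine, 0.015 for homeostatic and 0.36 for disease-associated genes. A minimum of 100 summed UMIs per gene gave 1.62 for pan-reactive genes of TBI-GFP against control and 0.68 for microglia cytokine genes, and a minimum of 1 summed UMI gave 0.27 for disease-associated genes, both of TBI-ND1 against TBI-GFP. The mean of per-cell CPM gave 1.76 (pan-reactive) and −0.55 (oxidative phosphorylation) in astrocyte-like cells of TBI-GFP against control. In TBI-ND1 against TBI-GFP it gave −0.32 for pan-reactive, −0.21 for A1, 0.28 for oxidative phosphorylation and −0.76 for cytokine genes. Thinning to 1000 UMIs gave 1.40 for pan-reactive genes of TBI-GFP against control, and in TBI-ND1 against TBI-GFP −0.17 for astrocyte cytokine, −0.043 for Usp18 in astrocyte-like cells and −0.36 for microglia interferon genes. The limit of 10% mitochondrial UMIs and totals without mitochondrial and ribosomal protein genes changed the direction of none of these results.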

Other observations

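All tests of explanations in this part, and the split of astrocyte-like cells by the reporter, were chosen after the results were seen. In TBI-ND1, 190 astrocyte-like cells held a GFP UMI and 1547 held none, at medians of 3338 and 3214 UMIs. The split follows the clusters in large part, since 160 of the 190 cells lie in the Gal-led cluster 17 and 10 in the Aldoc-led cluster 13. In cells with the reporter, Gal stood at 17311 CPM against 818 CPM without it (log2 ratio 4.40, 4.36 to 4.45) and Sct at 1415 CPM against 81.8 CPM. Hes6, a gene of neural progenitors, was higher by 1.76 (1.42 to 2.08). Gfap was higher by 1.49, while Aqp4 and Aldoc, genes of mature astrocytes, were lower (−1.57 and −2.33). The homeostatic astrocyte list had a median of −0.76 (−0.81 to −0.67) and cholesterol synthesis genes a median of −1.17. RNA of another cell type was higher with the reporter, with the homeostatic microglia list at 1.74 (1.30 to 1.85; 13 of 16 genes higher), while in TBI-GFP that list stood at −0.54. In TBI-ND1 the complement list stood at 1.15, MHC class I genes at 1.33, immediate-early and dissociation stress genes at 0.73 (0.58 to 0.87; 11 of 18 genes higher), cytokine and NF-kB genes at 1.03 and ribosomal protein genes at 0.52. The last 3 lists stood at −0.11, 0.04 and 0.11 in TBI-GFP. In TBI-ND1 the neurogenic list stood at 0.23 with an interval of −0.11 to 0.67, with 4 of 12 genes higher and 1 lower. Neurod2 was higher by 2.16 (0.62 to 3.44), at 9.99 and 2.36 CPM, and Rcor2 by 1.75 (1.01 to 2.39). Dcx had 0 UMIs with the reporter and 9 UMIs without it, too few to show a difference. The neuronal gene Snap25 stood at 18.7 and 20.5 CPM. In TBI-GFP, 1291 astrocyte-like cells held a GFP UMI and 5126 held none, at medians of 1759 and 1419 UMIs. Of oligodendrocyte-like cells there, 11.7% also held one, so a GFP UMI does not by itself mark a cell as carrying the vector. Among the astrocyte clusters of TBI-GFP, GFP was lowest in the Gpc5-led and highest in the Gfap-rich cluster, as given above. The split in TBI-GFP may thus also reflect the clusters and the depth. In TBI-GFP, Gal stood at 58.4 CPM with the reporter and 17.7 CPM without it, Aqp4 was higher by 0.26 and Aldoc lower (−0.20). The A2 list moved in opposite directions with the reporter in the 2 TBI libraries. It stood at 0.99 in TBI-GFP, with 8 of 10 genes higher and 1 lower. In TBI-ND1 it stood at −1.10 (−1.79 to −0.24), with 1 of 6 genes higher and 4 lower. Several other lists moved the same way with the reporter in both libraries. In TBI-GFP the pan-reactive list stood at 1.01 (12 of 13 genes higher) and interferon response genes at 0.63, against 0.63 and 0.57 in TBI-ND1. MHC class I genes stood at 0.53, homeostatic astrocyte genes at −0.21 and cholesterol synthesis genes at −0.46 in TBI-GFP, and Gfap was higher there by 0.68. The complement list stood at 0.06 in TBI-GFP.

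The Gal level of reporter-bearing astrocyte-like cells in TBI-ND1 was weighed against free RNA, the vector and NeuroD1. Gal CPM in these cells was 62.2 times that of the highest cluster outside the class, and microglia-like cells held 15.6 CPM. No cluster outside the class thus held Gal near that level on average. Whether free RNA or doublets with another captured cell type were the source of Gal cannot be decided from this. Gal was picked by its ratio, and most of these cells lie in the Gal-led cluster, so a high value was in part fixed in advance. A rare cell type within a cluster would also not show in the average of that cluster. Doublets with microglia among these cells are not excluded, and other genes of the split may carry their RNA. The reporter or vector alone and NeuroD1 expressed from the vector cannot be told apart from each other or from another difference between these libraries: Gal CPM in reporter-bearing cells of TBI-ND1 was 296 times that of TBI-GFP, but Gal was picked by its ratio between these libraries, and the ND1 feature had 1 UMI in TBI-ND1. A difference in the tissue sampled was not tested and stays open.

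The lower nuclear oxidative phosphorylation genes of TBI-GFP astrocyte-like cells were weighed against 3 technical explanations. The lower UMI floor of TBI-GFP as the whole cause is argued against, since the median was −0.39 at 2000 UMIs or more per cell. A shift shared by all classes cannot be told apart from a change in astrocytes: the median over the other classes was −0.15, but their values ran from −0.65 to −0.01, a range that includes the astrocyte value of −0.43. A candidate explanation is which clusters make up the class, on top of such a shift, since in the Aldoc-led clusters alone the median was −0.22. The injury itself was not tested apart from these and stays open, with 1 library per group and a control gene table of its own.

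Ttr, the main secreted product of choroid plexus, was present throughout TBI-ND1, at 5063 CPM in astrocyte-like cells and 9399 CPM in microglia-like cells, against 41.7 CPM and 45.9 CPM in TBI-GFP. An unnamed cluster of 230 cells in TBI-ND1 was led by the plasma cell genes Jchain, Ighm and Igha. In the authors' deposited table of mean values, Ttr stands at 0.456 in TBI-GFP, 72.7 in TBI-ND1 and 0.160 in control, and Lcn2 at 0.271, 0.966 and 0.0387.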
